A study of Mus musculus with 4 samples.

How the data were processed

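Expression was measured by poly(A) RNA-seq in 4 libraries of mouse brain endothelial cells, as the labels name them, taken by laser capture. Per the labels' protocols, RNA was extracted with a Zymo Research miniprep kit and libraries were made with the NEBNext UltraExpress kit from enriched mRNA with random priming. The labels do not state the strand setting, so genes and antisense partners may share reads. The authors deposited 1 table of FPKM (fragments scaled by transcript length and by mapped total) with 46072 genes and 4 libraries. The submitters' processing notes name bcl2fastq 2.20, HISAT2 2.2.1, SAMtools, StringTie 2.2.1 and build GRCm38. The role and order of these tools, the annotation release, filters and the treatment of reads with several matches are not given in the sources used here. FPKM divides by transcript length and by the mapped total, so a few high genes lower every other value and a loss of long transcripts lowers long genes. The low values showed no whole-read steps, read depth is unknown, and an exact 0 can be a failed estimate, so such genes are described as listed at 0.

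Each library was given its group and replicate from the labels and its column from the library name there, and 0 columns were left out. Gene positions and transcript lengths came from GENCODE M21 (GRCm38), which covered 45223 genes of the table, and names from the table and a supplied name table that matched 45137. Transcript length here is that of a gene's longest annotated transcript, which need not be the length behind its FPKM. Transcripts of genes with a mean of at least 1 FPKM were compared with mitochondrial transcripts by BLAST+ 2.17.0, at no less than 95% identity over 50% of their length, which found 10 nuclear copies. Values were analysed as log2(FPKM + 1), with a pseudocount of 1, so fold differences of low genes are understated.

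Because the series has 1 group, genes were tested against a fixed level or against other genes of the same library. limma 3.58.1 in R 4.3.3 gave a 2-sided moderated test with a mean-variance trend for each of 25206 genes above 0 in any library, first against 1 FPKM and then, within library, against the median of the pan-endothelial list, with Benjamini-Hochberg adjustment and a threshold of 0.05. The second test placed 7782 genes above and 15359 below the pan-endothelial median, with 2065 in neither. Before the data were examined, 32 gene lists with 339 entries were fixed, and all entries were found in the table. Lists were compared with the pan-endothelial list by the difference of medians per library, with an exact 2-sided sign-flip test (16 patterns, smallest p of 0.125, so it cannot reach 0.05). limma's fry over 31 lists, with Benjamini-Hochberg adjustment, asks whether a list's genes lie, on balance, on 1 side of the pan-endothelial median. It scales genes by their spread, so its direction can differ from that of the median, and it does not compare a list with other genes. Some lists share members, and astrocyte, neuronal or fibroblast genes can be active in other brain cells. A percentile among 10000 random lists of equal size describes these libraries.

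Genes named in the text followed a rule fixed before the data were examined. It takes 8 endothelial genes (Pecam1, Cldn5, Cdh5, Slc2a1, Mfsd2a, Abcb1a, Ocln and Tjp1), up to 4 highest and 2 lowest members of each list, the 20 highest genes, the 10 genes with the largest SD among those with a mean of at least 5 FPKM, and the sex-linked list. Genes outside it are named as such, and some genes that the rule takes are not reported here. The limma step was tested on simulated data for the comparison with 1 FPKM, with 25206 genes at the level, their own spreads reassigned at random, 200 of them shifted, and no mean-variance trend. Of 50 genes each, 12% were recovered at a log2 shift of -0.5, 30% at 0.5, 58% at 1 and 86% at 2, with 1 false call among 94. The noise was equal in both directions, so the shares at -0.5 and 0.5 differ only through the spreads and noise drawn. Far fewer genes were shifted than the 12034 above and 10104 below 1 FPKM in the real test, so the adjusted cutoff was stricter. These shares therefore do not give the power of the real test.

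Alternatives covered the pseudocount, filters, scaling, detection level, variance model, list summary, shared members and each library left out. Others, chosen after seeing the data, covered transcript length, list members under 1 FPKM, mitochondrial copies and shared members of the vessel segment lists. Members with a mean under 1 FPKM were left out of every list, the pan-endothelial one included. That choice removes low values, so it tends to raise the median of a list and of the reference alike. With the list mean in place of the median, fry set the same genes against the pan-endothelial mean and did not use the list's own mean. List means are given as differences from the pan-endothelial mean. No comparison between groups could be made. Figures were drawn with matplotlib 3.10.9.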

Results

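The series holds 4 poly(A) RNA-seq libraries from wild-type, untreated mouse brain vasculature, labelled as endothelial cells taken by laser capture microdissection, in which a laser cuts chosen cells out of a tissue section. The series title describes tissue fixed by perfusion and cells picked by immunolabelling. All 4 libraries form 1 group, here replicates 1 to 4, so every comparison is between genes or gene lists within the libraries. The labels do not say whether the libraries came from separate animals, and p-values measure only the spread between these samples, which may be technical. Values are the authors' FPKM, with sums per library of 448678 to 482882. Read depth is unknown, so no counting interval or detection floor is given.

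A library held 13639.5 ± 227 genes (SD, n = 4) at 1 FPKM or more, and 5767 ± 78.4 at 10 FPKM or more. Of 25206 genes above 0 in any library, 12034 lay above 1 FPKM, 10104 lay below it and 3068 passed in neither direction (limma, adjusted over all genes). With FPKM of each library rescaled to one fixed sum, as TPM has, a shift of 1.10 on the log2 scale, 13693 lay above and 7474 below. Across genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) between libraries was 0.983 to 0.987 and Spearman's rho 0.938 to 0.945. No pair shared more than 4 identical values above 0, so all 4 libraries were counted separately.

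The highest gene was Ttr, which encodes the thyroxine carrier transthyretin made in choroid plexus, at 14493 ± 2381 FPKM (SD, n = 4), or 3.11% ± 0.446 of summed FPKM. Of the 20 highest genes, 10 lie on the mitochondrial chromosome. Fth1, the ferritin heavy chain, measured 4412 ± 385 FPKM, and Mbp, myelin basic protein, 3187 ± 376 FPKM. Calm2, a calmodulin gene, measured 2371 ± 244 FPKM, Ptgds, a prostaglandin D synthase, 2019 ± 88.0 FPKM, and Tmsb4x, a thymosin, 1951 ± 147 FPKM. The 100 highest genes held 33.6% ± 2.43 of summed FPKM, the 13 mitochondrially encoded protein genes 8.13% ± 1.34, and ribosomal protein genes 2.43% ± 0.132. Another 4 of the top 20 are nuclear pseudogenes on chromosome 1 whose transcripts match mitochondrial ones. For example, Gm10925 (chromosome 1, 24613974 to 24614651, GRCm38) matched mt-Atp6 at 100% identity and measured 6550 ± 993 FPKM against 6276 ± 1022 for mt-Atp6. The values of these copies and of their mitochondrial partners are uncertain, since reads may be shared. The 10 nuclear copies found held 4.72% ± 0.809 of summed FPKM, which the 8.13% above does not include.

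The first question, which follows from the labels, was how far endothelial genes were measured. Most general endothelial markers were present at low to moderate level: 14 of the 17 in the pan-endothelial list lay above 1 FPKM, 1 lay below it and 2 passed in neither direction, with the same 14 and 1 adjusted over the list alone. The highest were Ly6c1 at 68.2 ± 4.29 FPKM, Ly6a at 49.5 ± 4.33, Ramp2, a receptor activity-modifying protein, at 41.8 ± 18.7, and Egfl7, a secreted endothelial protein, at 40.3 ± 4.67 (SD, n = 4 each). Cldn5, the main claudin of brain endothelial tight junctions (ENSMUSG00000041378, chromosome 16, 18776847 to 18778262, GRCm38), measured 19.0 ± 0.698 FPKM, 3.32 ± 0.05 (SE) above 1 FPKM on the log2(FPKM + 1) scale (adjusted p = 1.74e-07). Pecam1, the adhesion molecule CD31 (chromosome 11, 106654217 to 106750628), measured 4.31 ± 0.570 FPKM. Cdh5, vascular endothelial cadherin (chromosome 8, 104101625 to 104144511), measured 0.878 ± 0.367 FPKM and could not be told from 1 FPKM (adjusted p = 0.458), and with FPKM rescaled to the fixed sum its log2 difference of 0.50 did not pass either (adjusted p = 0.0668). Erg, an endothelial transcription factor, lay below 1 FPKM at 0.368 ± 0.123, a call lost with that rescaling (adjusted p = 0.266). The list median was 4.49 ± 0.195 FPKM, at the 90.2th percentile of 10000 random lists of 17 genes, which was 68.7 with genes of at least 0.1 FPKM alone and 99.9 with no filter. Ramp2 overlaps Vps25 on the same strand, and its value is uncertain for that reason.

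The lists of blood-brain barrier transporters and of caveolae genes were measured above the general endothelial markers, though the values do not tell which cells the RNA came from. All 14 barrier transporters lay above 1 FPKM, also adjusted over the list alone, with a list median of 11.2 ± 1.57 FPKM (SD, n = 4), 1.14 ± 0.14 (SD) above the pan-endothelial median on the log2(FPKM + 1) scale in 4 of 4 libraries, and the list mean was 0.58 above. Single transporters exceeded the pan-endothelial median in 11 cases and lay below it in 3. Slc3a2, the heavy chain of amino acid transporters, measured 43.4 ± 4.54 FPKM, Slc2a1, the glucose transporter GLUT1, 32.2 ± 2.92, Slco1c1, a thyroid hormone transporter, 27.5 ± 2.95, and Mfsd2a, a lysolipid transporter, 8.06 ± 2.09. Abcb1a, a drug efflux pump, measured 3.36 ± 1.04 FPKM, -0.36 from the pan-endothelial median (limma, adjusted p = 0.0489). All 7 caveolae genes lay above 1 FPKM, also over the list alone, with a median of 13.1 ± 3.10 FPKM, 1.34 ± 0.32 above the pan-endothelial median, and Cav2 at 41.4 ± 4.73. The 14 junction genes had 12 above and 1 below 1 FPKM, the same over the list alone. Among them Ctnnb1, beta-catenin, measured 70.1 ± 7.82 FPKM, Ocln, occludin, 6.50 ± 1.37, and Tjp1, the scaffold ZO-1, 4.22 ± 1.03. The junction median was 0.15 ± 0.15 above the pan-endothelial one in 3 of 4 libraries, but its mean was -0.29 from the pan-endothelial mean. The list test (limma fry, direction up, adjusted p = 0.00543) was lost without replicate 1 (adjusted p = 0.0554) and with members under 1 FPKM left out (adjusted p = 0.059). It was also lost against the pan-endothelial mean in place of the median, where its direction was down (adjusted p = 0.0601).

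Of the vessel segment lists, the capillary one was measured highest. These libraries also held neuronal and glial markers far above endothelial ones, and the source cells of the segment genes were not tested. All 8 capillary genes lay above 1 FPKM, also over the list alone, with a median of 16.02 ± 1.80 FPKM (SD, n = 4). Itm2a, a membrane protein gene of brain capillaries, measured 139 ± 14.5 FPKM, Rgcc, a cell cycle regulator, 31.7 ± 3.57, and Car4, carbonic anhydrase 4, 29.3 ± 3.58. The arterial list had 7 of 12 members above and 3 below 1 FPKM, the same over the list alone, with Hey1, a Notch target, at 19.0 ± 2.15 and Dll4, a Notch ligand, at 0.289 ± 0.181. The venous list had 7 of 10 above (6 adjusted over the list alone) and 1 below, with Vcam1, an adhesion molecule, at 22.1 ± 2.75 and Nr2f2, a venous transcription factor, at 7.14 ± 1.22. With genes shared between fixed lists left out, the capillary median was 3.06 ± 0.32 (SD) above the arterial one and 2.47 ± 0.35 above the venous one on the log2(FPKM + 1) scale, in 4 of 4 libraries, and the arterial median lay -0.59 ± 0.02 from the venous one. With shared genes kept, an alternative chosen after seeing the data, the capillary median was 2.23 above the arterial one and the arterial median lay -0.03 from the venous one. These comparisons rest on 5, 12 and 6 genes and have an exact sign-flip p of 0.13, the smallest that 4 libraries allow. Relative to the pan-endothelial median, the arterial list lay at -0.61 ± 0.18 (list mean -1.20) and the venous list at -0.58 ± 0.20 (list mean -0.90) (limma fry, direction down, adjusted p = 5.31e-05 and 0.000853). The venous call was lost without replicate 2, where the median difference was -0.63 but the list test pointed up (adjusted p = 0.334), and with shared genes left out the venous list lay at -0.02 (adjusted p = 0.208). With members under 1 FPKM left out both calls were lost (arterial -0.47, adjusted p = 0.0608, venous -0.31, adjusted p = 0.162).

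Markers of other vessel-related states were lower. The 14 Wnt pathway and barrier regulators had 7 above and 1 below 1 FPKM, with Tspan12, a Norrin co-receptor, at 16.9 ± 4.47 FPKM, Lef1, a Wnt effector, at 5.72 ± 0.375, and Lrp5, a Wnt co-receptor, at 0.124 ± 0.0522 (SD, n = 4). Their list lay at -0.94 ± 0.09 from the pan-endothelial median. Of 4 markers of fenestrated endothelium 2 lay above and 2 below 1 FPKM, and Plvap, the diaphragm protein of fenestrae, measured 11.9 ± 1.68. Of 9 activation genes 2 lay above and 3 below 1 FPKM. The 2 above were Vcam1, also on the venous list, at 22.1 ± 2.75 and Icam1 at 2.06 ± 0.433, while Sele, E-selectin, was listed at 0 in all 4 libraries. These lists lay at -1.40 ± 0.33 and -2.0 ± 0.27. Over the alternatives they ranged from -2.34 to -0.11 and from -3.84 to -1.12. Counts for these lists were the same adjusted over the list alone. All were lower by the list test (limma fry, direction down, adjusted p = 0.00012, 0.00218 and 6.95e-05), but with members under 1 FPKM left out the fenestrated list lay at -0.11 and lost its call (adjusted p = 0.0608).

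Markers of mural cells and vessel-associated matrix and fibroblasts were measured beside the endothelial ones. Of 10 pericyte genes 7 lay above and 1 below 1 FPKM, with Vtn, vitronectin, at 61.4 ± 9.07 FPKM and Rgs5, a G protein signalling regulator, at 19.7 ± 2.73 (SD, n = 4). Of 12 smooth muscle genes 10 lay above and 1 below, with Acta2, smooth muscle actin, at 55.2 ± 7.18 and Myl9, a myosin light chain, at 58.1 ± 6.29. Of 11 fibroblast genes 9 lay above and 1 below, with Igf2, a growth factor, at 39.4 ± 12.5 and Dcn, decorin, at 28.1 ± 2.05. Of 11 basement membrane genes 6 lay above (5 over the list alone) and 1 below, with Sparc, a matrix protein also made outside vessels, at 488 ± 41.2 and Hspg2, perlecan, at 0.159 ± 0.0913. The other counts were the same adjusted over the list alone. Pericyte and basement membrane lists lay at -0.40 ± 0.01 and -0.95 ± 0.32 from the pan-endothelial median and did not pass the list test (limma fry, adjusted p = 0.174 and 0.105), though the latter passed without replicate 3 (adjusted p = 0.0495). Against the pan-endothelial mean in place of its median both passed as lower (limma fry, adjusted p = 0.00413 and 0.0415). With members under 1 FPKM left out the pericyte list passed with direction up (adjusted p = 0.0193), but that filter removes its low members by choice. The smooth muscle median lay at -0.31 ± 0.14 and its mean at -0.28, whereas the list test pointed up (adjusted p = 0.00162). That call was lost against the pan-endothelial mean (adjusted p = 0.842) and with length adjustment (adjusted p = 0.0729). The fibroblast median lay at 0.46 ± 0.24 and its mean at -0.15, with the test pointing up (adjusted p = 0.00124). Against the pan-endothelial mean the test pointed down (adjusted p = 0.0122).

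The second question was how markers of other brain cells compared with the endothelial ones in the same libraries. Neuronal, oligodendrocyte and astrocyte markers were far above them. All 14 pan-neuronal, all 12 oligodendrocyte and all 15 astrocyte genes exceeded the pan-endothelial median (limma, adjusted over all genes), and all lay above 1 FPKM, also over the list alone. The pan-neuronal median was 146 ± 0.803 FPKM (SD, n = 4), 32.6 ± 1.30 times the pan-endothelial median, or 4.74 ± 0.06 higher on the log2(FPKM + 1) scale. That SD is of the list median and not of its members, of which Snap25, at 1433 ± 185 FPKM, and Thy1, at 24.4 ± 5.06, varied more. The oligodendrocyte median was 81.2 ± 10.3 FPKM and 3.90 ± 0.21 higher, and the astrocyte median was 74.6 ± 11.6 FPKM and 3.77 ± 0.22 higher. Each was higher in 4 of 4 libraries, with an exact sign-flip p of 0.13, the smallest possible, and passed the list test (limma fry, direction up, adjusted p = 1.22e-05, 2.83e-05 and 1.22e-05). The 14 neuronal genes held 0.708% ± 0.0654 of summed FPKM and the 17 endothelial genes 0.0576% ± 0.00591.

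Snap25, a synaptic vesicle fusion protein (ENSMUSG00000027273, chromosome 2, 136713453 to 136782428, GRCm38), measured 1433 ± 185 FPKM, and Syp, synaptophysin, 272 ± 30.1 (SD, n = 4). Mbp (chromosome 18, 82475146 to 82585637) and Mobp, both myelin genes, measured 3187 ± 376 and 999 ± 92.2 FPKM. Aldoc, an astrocyte aldolase, measured 471 ± 60.7 FPKM, Gja1, connexin 43, 113 ± 8.31, and Gfap, the glial intermediate filament, 112 ± 16.9. Excitatory and inhibitory neuron lists had medians of 24.4 ± 2.80 and 31.5 ± 4.35 FPKM, 2.21 ± 0.15 and 2.56 ± 0.25 above the pan-endothelial median (list means 1.37 and 1.73 above). In each, 9 of 9 genes lay above 1 FPKM, also over the list alone, and 6 exceeded the pan-endothelial median while 2 lay below it. Slc17a7, a vesicular glutamate transporter, measured 91.5 ± 7.88 FPKM, Nrgn, neurogranin, 388 ± 52.0, Gad1, which makes GABA, 87.3 ± 2.71, and Sst, somatostatin, 172 ± 12.5. Of 9 oligodendrocyte precursor genes 6 lay above and 1 below 1 FPKM, the same over the list alone, and the list at -0.29 ± 0.20 did not pass the test (limma fry, adjusted p = 0.457, direction up). It passed with direction up at pseudocounts of 0.1 and 0.01 (adjusted p = 0.025 and 0.0118). Against the pan-endothelial mean, from which the list mean lay at -0.53, it passed with direction down (adjusted p = 0.00276), so no direction is given. In that list Olig1, a transcription factor of the lineage, measured 50.2 ± 7.12 and Vcan, versican, 0.369 ± 0.160.

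**Figure D1:**
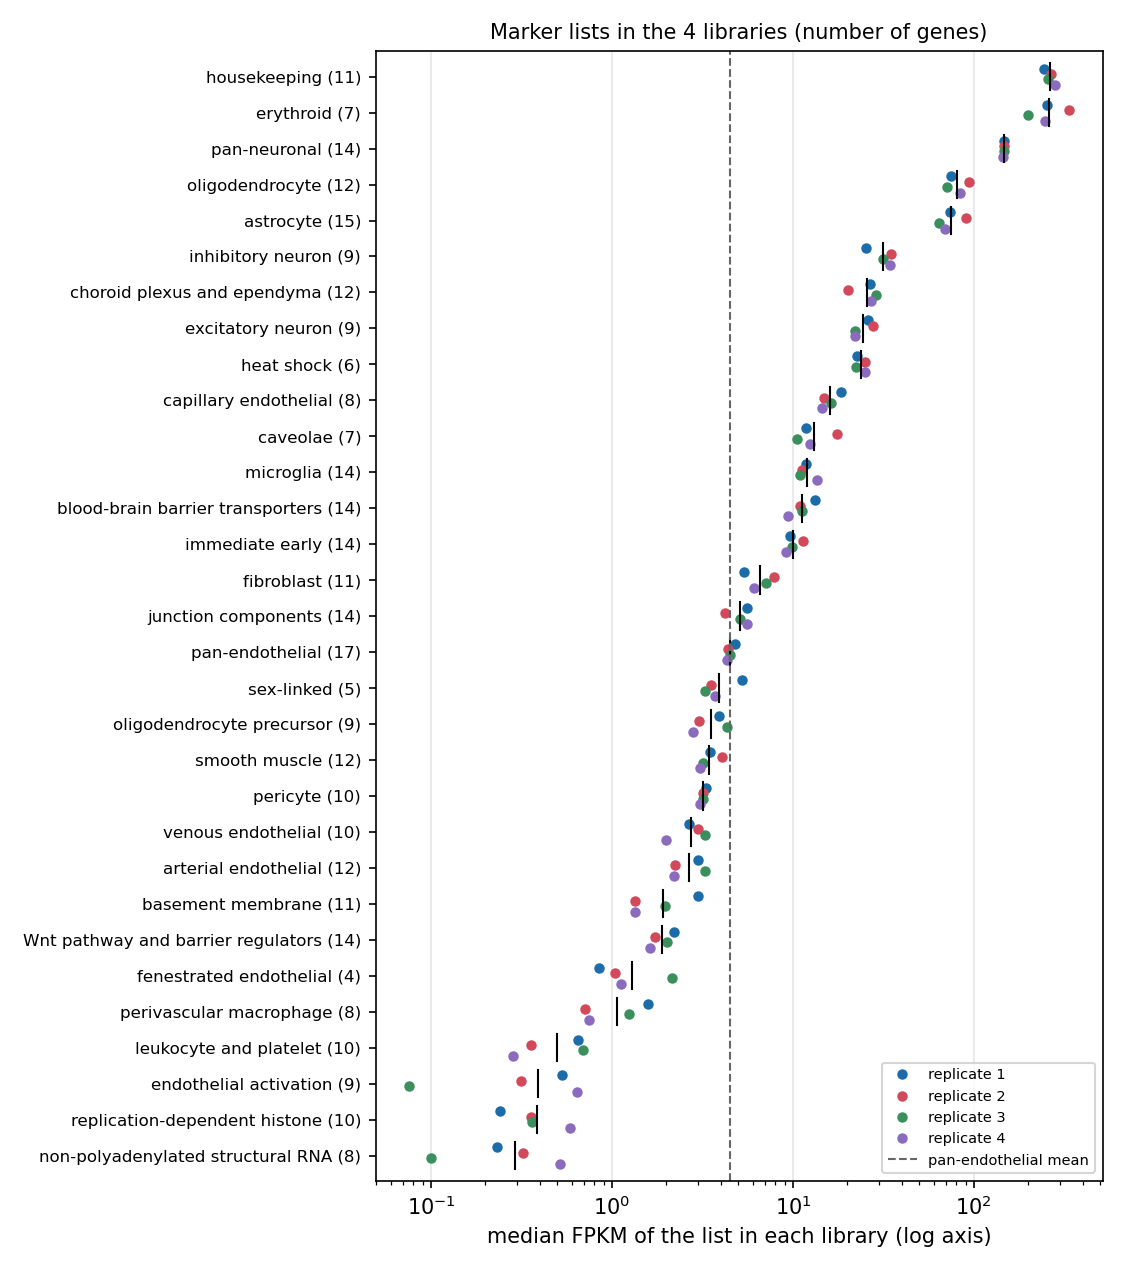
Median FPKM of each fixed gene list in each library, on a log axis, with 1 point per library, a black bar for the mean of 4 libraries and a dashed line at the pan-endothelial mean of 4.49 FPKM; numbers in parentheses count genes, and the mitochondrially encoded list (2153 FPKM) is left out. The pan-neuronal list lies at 146 FPKM, and the oligodendrocyte and astrocyte lists at 81.2 and 74.6 FPKM.

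Choroid plexus, blood and microglial genes were also measured above the endothelial level, and macrophage and leukocyte genes below it. All 12 choroid plexus and ependyma genes lay above 1 FPKM, also over the list alone, and 11 exceeded the pan-endothelial median, with a list median of 25.8 ± 3.80 FPKM (SD, n = 4), 2.27 ± 0.21 higher. Kcnj13, a potassium channel, measured 180.5 ± 28.6 FPKM and Folr1, a folate receptor, 117 ± 10.6. The haemoglobin genes Hbb-bs and Hbb-bt measured 503 ± 111 and 260 ± 57.2 FPKM, while Hba-a1 and Hba-a2, at 382 ± 91.2 and 380 ± 86.7, are near-identical copies with uncertain split. Of 7 erythroid genes 5 lay above and 2 below 1 FPKM, the same over the list alone, with Slc4a1, the red cell anion exchanger, at 0.0969, 0.221, 0.0368 and 0 FPKM in replicates 1 to 4. The erythroid median was 5.55 ± 0.32 higher and the mean 2.27 higher, with 4 genes above the pan-endothelial median and 2 below. All 14 microglial genes lay above 1 FPKM, also over the list alone, and 12 exceeded the pan-endothelial median, with C1qb, a complement subunit, at 67.0 ± 7.51 and a list difference of 1.23 ± 0.15. These 3 lists passed the list test (limma fry, direction up, adjusted p = 9.28e-05, 0.000685 and 0.000281). Of 8 perivascular macrophage genes 1 lay above and 2 below 1 FPKM, with Pf4, a chemokine, at 4.31 ± 1.20 and Cd163, a scavenger receptor, at 0.274 ± 0.162. Of 10 leukocyte and platelet genes 3 lay above and 5 below, and Ly6g was listed at 0 in all 4 libraries. Both counts were the same over the list alone. These lists lay at -1.43 ± 0.24 and -1.89 ± 0.16 (limma fry, direction down, adjusted p = 0.000216 and 2.42e-05). Over the alternatives they ranged from -2.14 to -1.21 and from -3.28 to -0.81.

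**Figure D2:**
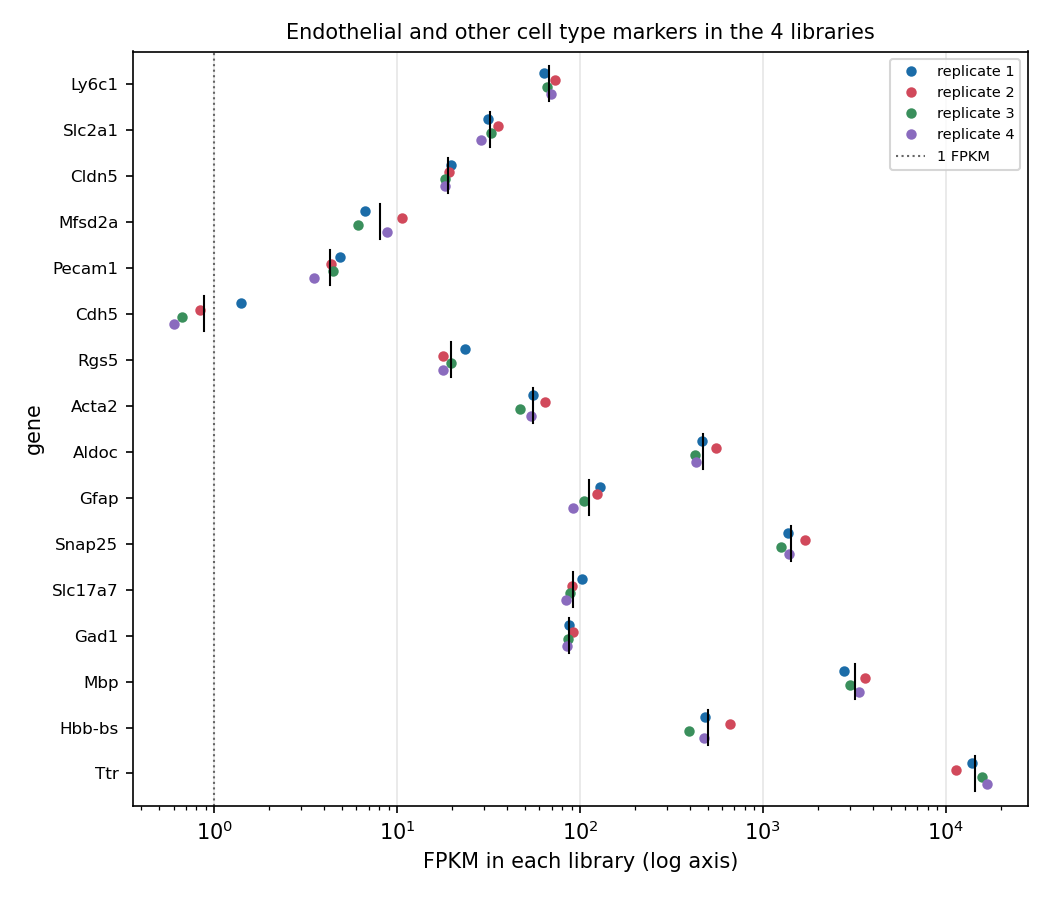
FPKM of 16 marker genes in each library, on a log axis, with 1 point per library, a black bar for the mean of 4 libraries and a dotted line at 1 FPKM. Snap25 (1433 FPKM), Mbp (3187 FPKM) and Ttr (14493 FPKM) lie far to the right of Cldn5 (19.0 FPKM), and Cdh5 (0.878 FPKM) lies beside the line.

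Genes of cell state and RNA type completed the lists. Of 14 immediate early genes 10 lay above and 1 below 1 FPKM, with Egr1 and Arc, both induced by activity, at 27.5 ± 2.97 and 20.7 ± 1.36 FPKM (SD, n = 4), and the list median was 0.99 ± 0.14 above the pan-endothelial one, though its mean was only 0.04 above. Of 6 heat shock genes 5 lay above 1 FPKM and none below, with Hsp90aa1, a chaperone, at 265 ± 28.7 and Hspa1b, an inducible chaperone, at 1.43 ± 0.204. All 11 housekeeping genes lay above 1 FPKM, with Gapdh at 772 ± 39.9, and so did all 13 mitochondrially encoded genes. Of 10 replication-dependent histone genes 2 lay above and 5 below, and Hist1h1a was listed at 0 in all libraries. Of 8 structural RNAs that lack poly(A) tails 3 lay above and 3 below, with 2 listed at 0, Rmrp and Rnu11. Rn7s1 and Rn7s2, near-identical copies of 7SL RNA with uncertain split, measured 146 ± 19.5 and 150 ± 24.1. Counts for all of these lists were the same over the list alone. By the list test (limma fry) heat shock, housekeeping, mitochondrial and immediate early lists were up (adjusted p = 8.09e-05, 2.42e-05, 3.04e-05 and 0.00112) and the histone list down (8.31e-05), with medians 2.08 ± 0.11, 5.58 ± 0.13, 8.59 ± 0.32, 0.99 ± 0.14 and -1.99 ± 0.19 from the pan-endothelial one. The heat shock list mean was 1.26 above. The structural RNA median lay at -2.13 ± 0.21 and its mean at -0.80, with the test pointing up (adjusted p = 0.0256). That call was lost without replicate 1 (adjusted p = 0.389) and turned down against the pan-endothelial mean (adjusted p = 0.0121). With members under 1 FPKM left out the structural RNA median lay at 4.44, and with a pseudocount of 0.01 at -5.49. The histone list ranged from -3.59 to -1.01 over the alternatives.

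All 4 libraries carried Y-linked transcripts. Ddx3y, an RNA helicase, measured 24.1 ± 2.21 FPKM, Eif2s3y, a translation factor, 15.8 ± 0.415, and Uty, a demethylase, 3.93 ± 0.875 (SD, n = 4), all above 1 FPKM, while Kdm5d, at 1.79 ± 0.805, passed in neither direction. Xist, the RNA of the inactive X chromosome, lay below 1 FPKM at 0.0882 ± 0.0973. Counts over the list alone were the same, 3 above and 1 below. The list median lay at -0.17 ± 0.20 from the pan-endothelial median and its mean at -0.49 from the pan-endothelial mean. The list test pointed up (limma fry, adjusted p = 0.00691). That call was lost without replicate 2 (adjusted p = 0.0908) and with length adjustment (adjusted p = 0.971). It turned down against the pan-endothelial mean (adjusted p = 0.0442), while the median lay at 0.43 with members under 1 FPKM left out.

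The third question was which genes differed between libraries of the group. The neuropeptide gene Oxt, oxytocin (chromosome 2, 130576173 to 130577054, GRCm38), measured 20.01, 0.477, 17.3 and 9.58 FPKM in replicates 1 to 4. Cpeb4, an mRNA-binding regulator, measured 7.53, 0.941, 10.5 and 8.43 FPKM. The histone gene Hist2h2aa1 measured 16.8 and 29.6 FPKM in replicates 1 and 3 and was listed at 0 in replicates 2 and 4, but it overlaps Gm20634 on the same strand and Gm20633 on the other, so its value is uncertain. Among 8362 genes with a mean of at least 5 FPKM the median SD of log2(FPKM + 1) was 0.18, and the 10 largest ran from 1.18 to 2.64. Vps25, an endosomal sorting subunit (chromosome 11, 101253707 to 101259549), measured 48.3, 14.01, 8.42 and 64.9 FPKM, and Ramp2, which overlaps it on the same strand, 22.2, 57.3, 58.2 and 29.4. Of the other genes among the 10, Gm15564, Gm20716, Gm20431, Gm21981 and Rnf113a2 also overlap another measured gene and are uncertain, and CAAA01147332.1 lies on an unplaced sequence.

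Libraries also differed with transcript length. In the longest quartile of 8340 genes, above 4227 bases, the median deviation from the other 3 libraries was 0.16 in replicate 1 and 0.09 in replicate 3, and -0.11 and -0.12 in replicates 2 and 4, on the log2(FPKM + 1) scale. Spearman's rho of deviation and length, across genes, was 0.433, -0.221, 0.210 and -0.418. Across the same genes the level itself had a rho of -0.329 with length. Length adjustment left the pan-neuronal list 4.57 ± 0.17 (SD, n = 4) above the pan-endothelial one, but moved the junction list to -0.05 ± 0.22 and the fibroblast list to 0.25 ± 0.21, where neither passed the list test (limma fry, adjusted p = 0.753 and 0.147).

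**Figure D3:**
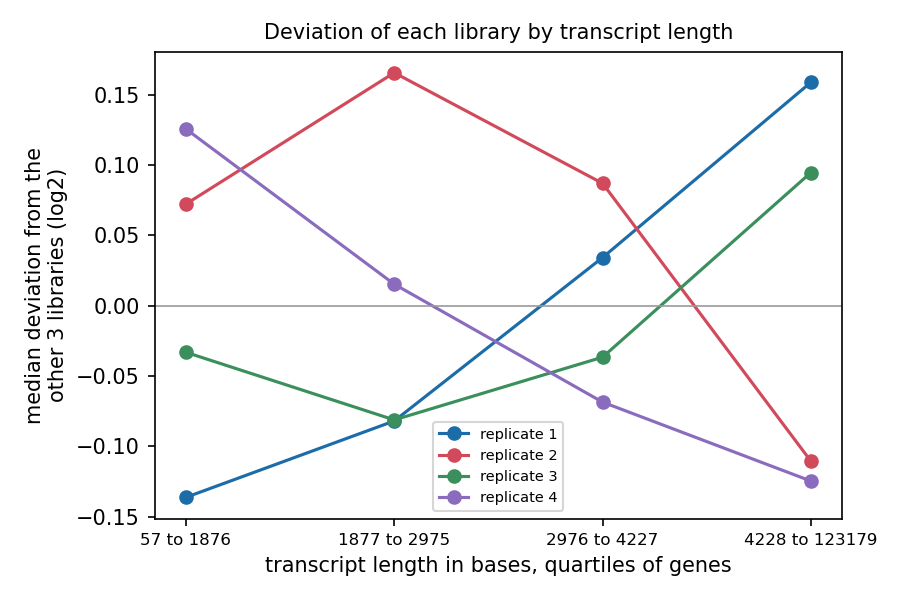
Median deviation of each library from the mean of the other 3, on the log2(FPKM + 1) scale, for quartiles of genes by transcript length in bases, with 1 line per library. In the longest quartile replicates 1 and 3 lie at 0.16 and 0.09, and replicates 2 and 4 at -0.11 and -0.12.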

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

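Of the tests in this part, the count of variable genes after length adjustment and the test of overlapping genes were chosen only after the result was seen. For 138 quantities, the gap between the highest or lowest library and its nearest neighbour was compared, as a share of the range, with Dixon's 95% critical value for 4 samples. Replicate 2 lay apart in 2 of them. It had the fewest genes above 0, 20860 against 21470 to 21570 in the others. Olig1 measured 60.85 FPKM there against 46.26 to 47.33. Chance alone marks about 5%, or 1 in 20, so 2 of 138 is no more than chance gives.

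Replicate 2 was also the lowest library for 30 of the 50 genes with the largest SD of log2(FPKM + 1), against 8, 7 and 5 for replicates 1, 3 and 4. Loss of long transcripts stays open. The rho of deviation and length in replicate 2, -0.2205, did not decide it, since replicate 4 had a lower rho of -0.418. Replicate 4 was lowest for only 5 of the 50. After length adjustment replicate 2 was still lowest for 28, but this count cannot decide it either. The length trend was small, with a median deviation of -0.11 for the longest quartile in replicate 2. Removing it could hardly change which library is lowest for genes picked for their large SD. Reads divided between overlapping genes stay open. Of the annotated variable genes, 35.42% (17 of 48) overlapped another annotated gene with a mean of at least 1 FPKM. Among the other genes 22.82% did (Fisher's exact test, 2-sided p = 0.0558). The other 31 variable genes overlapped no gene of that level. Less nuclear RNA in replicate 2 stays open: the median deviation of 7 nuclear RNAs was -0.5935, lower than the mean of the others in 7 of 7 but the lowest of 4 libraries in only 4 of 7, -0.3432 after length adjustment, and -0.60 in the 5 left without Rian and Mirg, whose neighbour Meg3 had been seen to be low. A fall in replicate 2 was not special to nuclear RNA, as the mitochondrially encoded list deviated by -0.66 and the choroid plexus list by -0.44 there. Other list medians rose in replicate 2, such as the caveolae one by 0.56 and the erythroid one by 0.54. The caveolae median was the value of Cav1 in each library, and its other members did not move together. In replicate 2 Cav2 and Cavin3 were highest, at 44.6 and 35.2 FPKM, but Cavin1 and Ehd4 were lowest, at 6.15 and 3.90 FPKM. The variable genes themselves were not tested, nor, with 1 group, was any biological explanation.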

How the results depend on the processing

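Of the alternatives, adjustment for transcript length, leaving out list members under 1 FPKM, leaving out mitochondrial copies and keeping shared members of the vessel segment lists were chosen only after the result was seen. Over 13 alternatives each, the pan-neuronal difference from the pan-endothelial list ranged from 4.02 to 5.01, the oligodendrocyte one from 3.60 to 4.17, the astrocyte one from 2.96 to 4.04, the choroid plexus one from 1.98 to 2.70, the capillary one from 1.33 to 2.45 and the transporter one from 0.58 to 1.31, all on the same side of the threshold. Read depth is unknown, so its effect on low genes was not analysed here. No paired analysis was possible because the series has 1 group. Where a value below differs for a reason other than the genes or libraries left in, the cause was not tested.

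Without a filter, 30135 genes lay below 1 FPKM and 36521 below the pan-endothelial level, since genes at 0 then count, and with a mean of at least 0.1 FPKM 5197 lay below 1 FPKM. Against 5 FPKM, 7322 genes lay above and 15705 below, with 7 pan-endothelial members above. Detected genes per library were 15558.5 at 0.5 FPKM, 8332.75 at 5 FPKM and 15758 with rescaling to a fixed sum. That rescaling put Cdh5 at 0.4964 above the level, and ended the calls below it of Erg, Vcan, Dll4 and Cd163. A pseudocount of 0.1 put Gm20716 at -0.04692 and the capillary minus arterial difference at 3.452, and gave a replicate Pearson's r of 0.9605. That r was 0.9816 and 0.9775 with filters at 0.1 and 1 FPKM. The 100 highest genes held 29.04% of summed FPKM without mitochondrially encoded genes and 30.98% without mitochondrial copies. Filters at 1 and 20 FPKM shared 6 and 2 of the 10 most variable genes. The pan-endothelial percentile was 68.68 with a filter at 0.1 FPKM and 99.87 with none.

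With the list mean for the median, junction (-0.291) and fibroblast (-0.1537) lists changed sign. The list test then used the pan-endothelial mean as its reference, and not the list's own mean. There the fibroblast list passed with direction down, as did basement membrane (-0.8249), pericyte (-0.6155), oligodendrocyte precursor (-0.53), structural RNA (-0.7951) and sex-linked (-0.4886) lists. The junction and smooth muscle lists no longer passed. The excitatory neuron (1.37), heat shock (1.26), erythroid (2.27) and arterial (-1.20) lists moved with the mean and kept their calls. The arterial minus venous difference was -0.742 with a pseudocount of 0.1, -0.565 with list means, -0.6724 with rescaling and -0.03135 with shared members kept, which also put capillary minus arterial at 2.233 and capillary minus venous at 2.202. With shared members left out the venous list lay at -0.02073 and lost its call. With length adjustment the junction list lay at -0.05494 and the fibroblast list at 0.2479, and both lost their calls, as did the smooth muscle and sex-linked lists. With pseudocounts of 0.1 and 0.01 the oligodendrocyte precursor list passed with direction up, and lists near the floor lay lower. At 0.01 they reached down to -5.49 for structural RNA, with activation at -3.84 and leukocytes at -3.28. With members under 1 FPKM left out, junction (0.004784), arterial (-0.4692), venous (-0.3137) and fenestrated (-0.1058) lists lost their calls, and the pericyte list passed with direction up. Oligodendrocyte precursor (0.1396), structural RNA (4.44) and sex-linked (0.4301) lists changed sign, the last also losing its call. This filter removes low members by choice, also from the pan-endothelial list, so upward moves follow in part from the filter. With each library left out in turn, the junction list ranged from 0.1016 to 0.2176 and lost its call without replicate 1 (0.1355), the venous list from -0.6396 to -0.4985 and lost it without replicate 2 (-0.6301), and the basement membrane list from -1.093 to -0.8705 and gained it without replicate 3 (-0.9733). The structural RNA list lost its call without replicate 1 and the sex-linked list without replicate 2.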

Other observations

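Of the tests in this part, the comparison of 4 marker lists with the pan-endothelial list was chosen only after the result was seen. Nuclear RNAs outside the fixed lists, examined for a test and not by the rule for named genes, were measured in all 4 libraries. Malat1, a long noncoding RNA kept in the nucleus, measured 463, 321, 521 and 476 FPKM in replicates 1 to 4, Snhg11 81.3, 57.0, 99.8 and 79.7 FPKM, and Neat1, the RNA of paraspeckles, 10.7, 6.87, 11.4 and 14.4 FPKM.

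Markers of neurons and glia were measured above the pan-endothelial markers in libraries labelled as captured endothelial cells. A lower FPKM of endothelial genes through transcript length was argued against, since the pan-neuronal list stayed 4.573 ± 0.17 (SD, n = 4) above after length adjustment, and 4.453 above in the lowest library. RNA of other cells in the captured material stays open: the pan-neuronal, oligodendrocyte, astrocyte and choroid plexus lists, which share 0 members with others, lay above the pan-endothelial list in 16 of 16 list-by-library differences, led by Snap25 at 1433 FPKM, Mbp at 3187 FPKM and Ttr at 14493 FPKM, but this restates the pattern, was known when the test was written and so decides nothing. Capture by immunolabelling would be meant to leave such cells out. Uncaptured tissue sequenced under the endothelial label cannot be told apart from this, because the table holds 0 libraries of uncaptured tissue, and with 1 group no biological explanation was tested.

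The hypothalamic neuropeptide genes Avp and Oxt were low in replicate 2. Avp, chosen after its values were seen, measured 39.7, 5.97, 33.1 and 25.9 FPKM in replicates 1 to 4, and the deviations of Avp and Oxt in replicate 2 were -2.26 and -3.43 on the log2(FPKM + 1) scale. Less hypothalamic tissue in replicate 2 could give this, but the median deviation of other hypothalamic genes was -0.01088, with 3 of 6 lower. That value lies past the bound set beforehand against the explanation, yet it excludes nothing, because only 6 of 14 such genes reached 1 FPKM, most of them near that level, with an SD of 0.285 between them. Animals, section level and capture site are not given in the sources used here, so a difference in any of them stays untested.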
